A study of Homo sapiens with 9 samples.

How the data were processed

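Poly(A) RNA sequencing was done on 9 cultures of SW620 cells in 3 groups of 3, untreated, 120 µM SM and 120 µM DSM, for 48 h. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the NuGEN Universal Plus mRNA-seq kit. The submitters' processing notes name bcl2fastq 2.20.0.422, cutadapt 3.4, FastQC 0.11.9, MultiQC 1.10.1, TopHat2 2.1.1, featureCounts 2.0.0, DESeq2 1.26.0 and the build hg38. The strand setting, the treatment of multi-mapping reads and the gene annotation are not given in the sources used here, so overlapping, antisense and near-identical genes are uncertain.

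The values tested were the deposited raw counts, whole-number read counts per gene for 28307 genes, which the authors left without normalization. The authors also deposited a normalized signal, which equals the counts divided by 1 size factor per library. Those factors equal DESeq2 size factors computed here from the counts, and that table was used for nothing else. Messenger RNAs encoded by mitochondrial DNA were not analysed here, and 0 of the 13 listed genes are in the table used.

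Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr by group (minimum count 10, minimum total 15), which left 15619, and libraries were scaled by TMM, with factors from 0.981 to 1.02. All 9 libraries entered 1 quasi-likelihood fit with robust estimation and group as its only term. Each comparison was a two-sided F test with Benjamini-Hochberg adjustment at 0.05. Log2 CPM used a prior count of 2. Gene IDs of 15413 tested genes matched RefSeq records of GRCh38.p14, from which coordinates were taken.

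Of 53 gene lists fixed in advance, 52 had at least 5 tested members. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, which tests whether a list's genes move on balance 1 way. A list score is the mean log2 CPM of its members per library, with a limma 95% interval. The groups, tests, lists and the rule for named genes were chosen before the data were examined. Under that rule the text names called genes of at least 5 CPM in either group whose libraries do not overlap, up to 10 per direction, leaving out pseudogenes and identifiers that are not gene names. It also names up to 4 called members of each described list, or the 2 most abundant where none was called, and a fixed set of 18 other genes whatever their call. Where no gene passed, the 5 with the smallest p are given. Applying the rule to the blocked fit, with the same direction in every pair in place of libraries that do not overlap, was chosen after the data were seen.

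Total counts lay between 39315662 and 65562227 per library, genes detected between 18316 and 19613, and the 10 most abundant genes took 5.41% to 5.83% of counts. Among replicates of a group, counts differed by more than sampling noise (chi-square per degree of freedom 6.50 to 34.0), and no libraries were identical. The labels number the replicates 1 to 3 in each group but do not say what a number shares. The numbers pair the libraries by the rule set in advance: all 9 correlations of deviations from the group means between same-numbered libraries lay between 0.227 and 0.582, above 0.1, against -0.404 to 0.161 for different numbers. In 18 of 18 cases the best-correlated library of another group had the same number. A fit with the replicate number as a block was therefore computed beside each result.

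The tests were tried on simulated counts with 200 changed genes among 15475. The simulation kept the blocked fit's differences between replicate numbers and drew its noise from that fit's dispersion trend, with no gene-specific spread. A gain from the block was therefore built in, and the rates below may not hold for the real libraries. For SM against untreated, the fit without the block recovered 13.4%, 37.3% and 66.7% of genes changed 1.25-, 1.5- and 2-fold with 0 false calls. The blocked fit recovered 59.7%, 65.7% and 92.4% with 7 false calls. For SM against DSM the values were 13.4%, 38.8% and 71.2% with 0 false calls, and 59.7%, 64.2% and 93.9% with 12. The median half-width of the 95% interval of a log2 fold change was 0.237 for SM against untreated without the block and 0.124 with it.

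Alternatives were DESeq2 size factors or library totals in place of TMM, no or a stricter filter on low counts, DESeq2 1.42.0, limma voom, a fit of only the 2 groups compared, a fit without robust estimation, the replicate block, and leaving out each library. Blocked forms of DESeq2, voom, fry, the estimated correlation and leaving out each library, thinning to the smallest total, leaving out the libraries numbered 1, and the tests along the axis that separates those libraries from the others were added after the data were seen.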

Results

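RNA was sequenced from SW620 cells, an established human line from a metastasis of a colon adenocarcinoma, grown in suspension in low-attachment plates in a medium supplemented with insulin, basic FGF and EGF. The cells received 120 µM streptomycin (SM), 120 µM dihydrostreptomycin (DSM) or neither for 48 h. SM is an aminoglycoside antibiotic that binds the small subunit of bacterial ribosomes, and DSM differs from it only in that the aldehyde of the streptose sugar is reduced to an alcohol. The series' design text calls the concentration an EC50 without naming the response it was measured on. Each group held 3 libraries, which the design text calls biological replicates. Total counts were lowest in SM replicate 2 (39315662) and highest in untreated replicate 1 (65562227), and 15619 genes were tested.

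The libraries numbered 1 stood apart from those numbered 2 and 3 in all 3 groups. The first principal component, with 39.6% of the variance, separated them. The replicate number took 48.0% of the sum of squares, the group 19.5% and the rest 32.5%. The group share was not compared with that of random groupings. SM replicate 2, the library with the lowest total, stood apart on the second component. Because same-numbered libraries deviated together, values from a fit with the replicate number as a block are given wherever they change a call.

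The first comparison asked how SM changed the transcriptome of SW620 cells. Genes driven by NRF2, the transcription factor of the oxidative and electrophile stress response, were higher with SM by camera, and enzymes of cholesterol synthesis were lower. Both calls were lost when the correlation between genes was estimated (adjusted p = 0.0515 and adjusted p = 0.316 with an estimated correlation). AKR1C2, an aldo-keto reductase, averaged 17.6 ± 1.88 CPM with SM and 9.27 ± 0.993 CPM without (SD, n = 3), and its relative AKR1C3 106 ± 4.30 against 72.4 ± 3.18 CPM. GPX2, the gastrointestinal glutathione peroxidase, averaged 345 ± 3.55 against 282 ± 3.18 CPM. These 3 genes rose in all 3 pairs, with log2 fold changes of 0.92 (SE 0.10), 0.55 (SE 0.06) and 0.29 (SE 0.04) and edgeR adjusted p of 0.0286, 0.0286 and 0.0401. No gene passed as lower, and 365 genes had an unadjusted p under 0.05. With the replicate block 428 genes passed, 187 higher and 241 lower, with a median absolute log2 fold change of 0.22 and 5 genes at least 2-fold. Those 5 were AKR1C1, NMRAL2P and AKR1B10, all NRF2 targets, and CYP4F3 and SNORD144 (-1.90), both below 1 CPM on average in untreated cells; AKR1B10, CYP4F3 and SNORD144 were chosen after their values were seen. DESeq2 called 12 genes without the block. Among those higher, AKR1C2, AKR1C3, GPX2, OSGIN1, SQSTM1, UGDH, TXNRD1, HMOX1 and NQO1 were followed by ALDH3A1, an aldehyde dehydrogenase gene, chosen after its value was seen. The edgeR adjusted p was above 0.05 for AKR1C2 without untreated replicate 1 (0.163), untreated replicate 2 (0.0909), untreated replicate 3 (0.228), SM replicate 2 (0.149) or SM replicate 3 (0.15), for AKR1C3 without untreated replicate 1 (0.0534), untreated replicate 2 (0.202), untreated replicate 3 (0.228), SM replicate 2 (0.149) or SM replicate 3 (0.147), and for GPX2 without untreated replicate 1 (0.365), untreated replicate 2 (0.35), untreated replicate 3 (0.32), SM replicate 1 (0.0781), SM replicate 2 (0.227) or SM replicate 3 (0.286). With 1 library left out their log2 fold changes stayed between 0.83 and 1.01 for AKR1C2, 0.52 and 0.58 for AKR1C3, and 0.28 and 0.30 for GPX2. With the block the count of 428 became 187, 169 and 149 without untreated replicates 1, 2 and 3 and 268 without SM replicate 3.

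**Figure D1:**
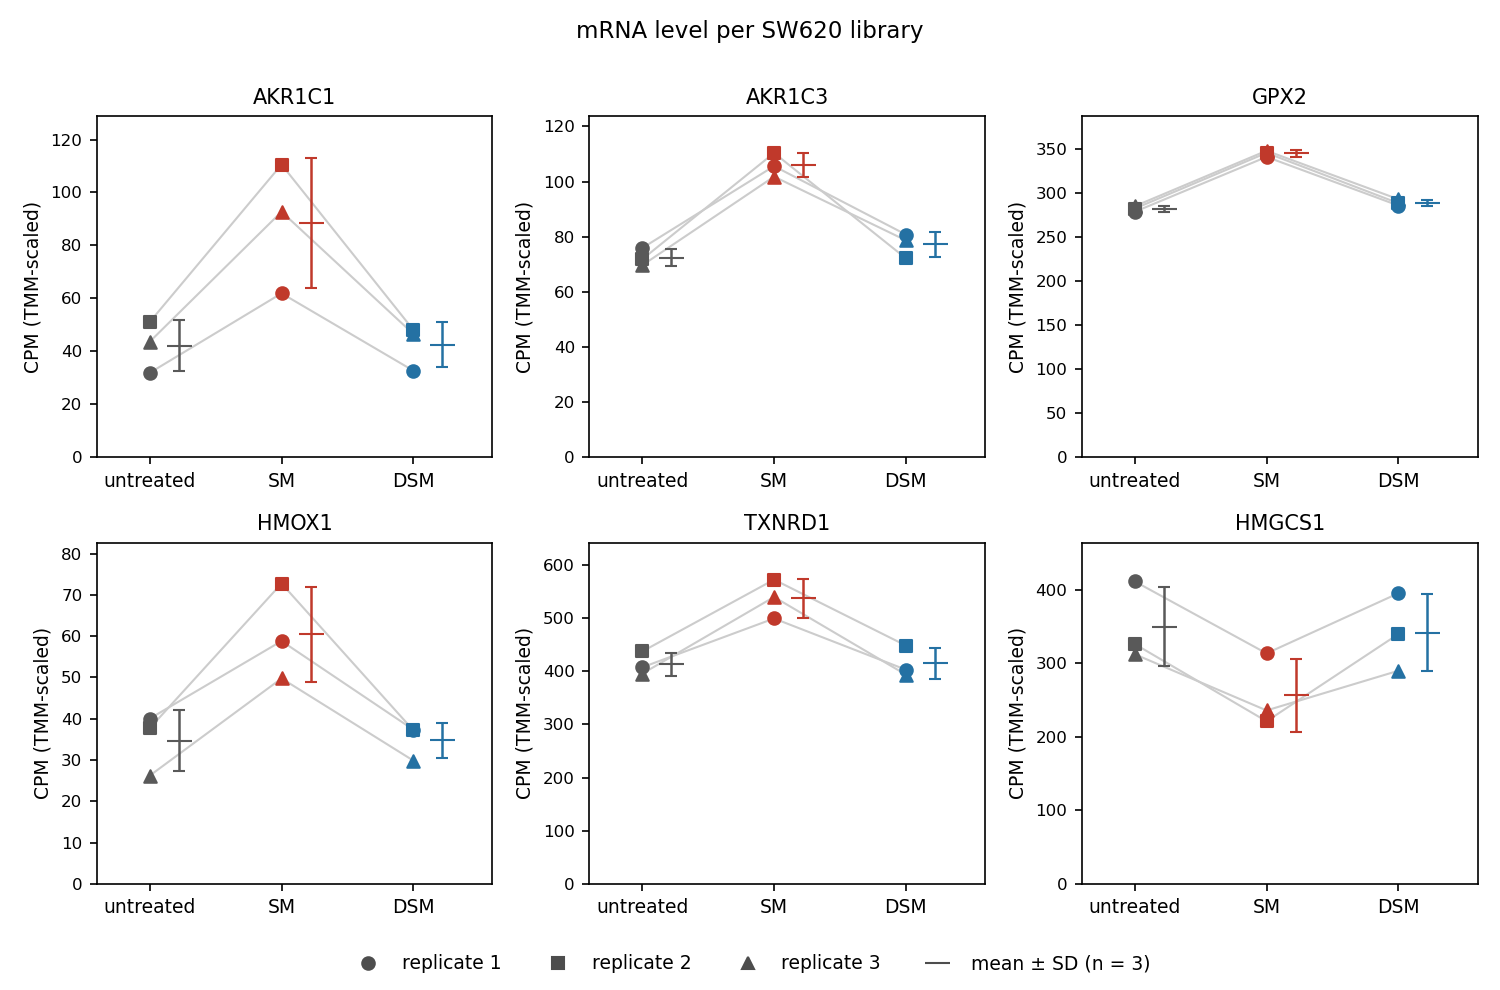
TMM-scaled CPM of 6 genes in each SW620 library by group, with symbols for the replicate number, grey lines joining libraries of the same number, and bars for the mean ± SD (n = 3). AKR1C1, AKR1C3, GPX2, HMOX1 and TXNRD1 sit higher and HMGCS1 lower in each SM library than in the untreated and DSM libraries of the same number.

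The list of NRF2 targets was fixed before the data were examined and held 33 tested genes, of which 32 had a positive fold change. Its score, the mean log2 CPM of its members, was 0.34 higher with SM (95% interval 0.20 to 0.48) and higher in 3 of 3 pairs. The camera test called the list (adjusted p = 2.47e-53, and adjusted p = 0.0515 with an estimated correlation). AKR1C2 and AKR1C3 were the 2 members that passed over all genes, and 17 passed when adjusted over the list alone. With the block 24 members rose and 0 fell, 27 when adjusted over the list alone (adjusted p = 0.0959 with an estimated correlation, and 0.0183 by fry). AKR1C1 had the smallest adjusted p there (2.45e-13), at 88.4 ± 24.6 against 42.2 ± 9.68 CPM, a log2 fold change of 1.06 (SE 0.05). HMOX1, which encodes the heme-degrading heme oxygenase, rose by 0.80 on the log2 scale (SE 0.06) in the blocked fit, and OSGIN1 by 0.63 (SE 0.07). NMRAL2P, a transcribed pseudogene in the list, rose by 1.23 (SE 0.10) from 3.56 ± 1.73 CPM. Others of the 24 were NQO1, GCLM, GCLC, TXNRD1, SRXN1, GSR, UGDH and the ferritin genes FTL and FTH1.

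AKR1C1, AKR1C2 and AKR1C3 lie next to each other on chromosome 10 of GRCh38.p14, at positions 4963415 to 4983283, 4987775 to 5018000 and 5048781 to 5107686. AKR1C1 and AKR1C2 are close to identical in sequence and AKR1C3 less so, and the split of reads between them is uncertain where the counting could share reads. GPX2 lies on chromosome 14 (64939158 to 64942745) and HMOX1 on chromosome 22 (35381096 to 35394207).

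**Figure D2:**
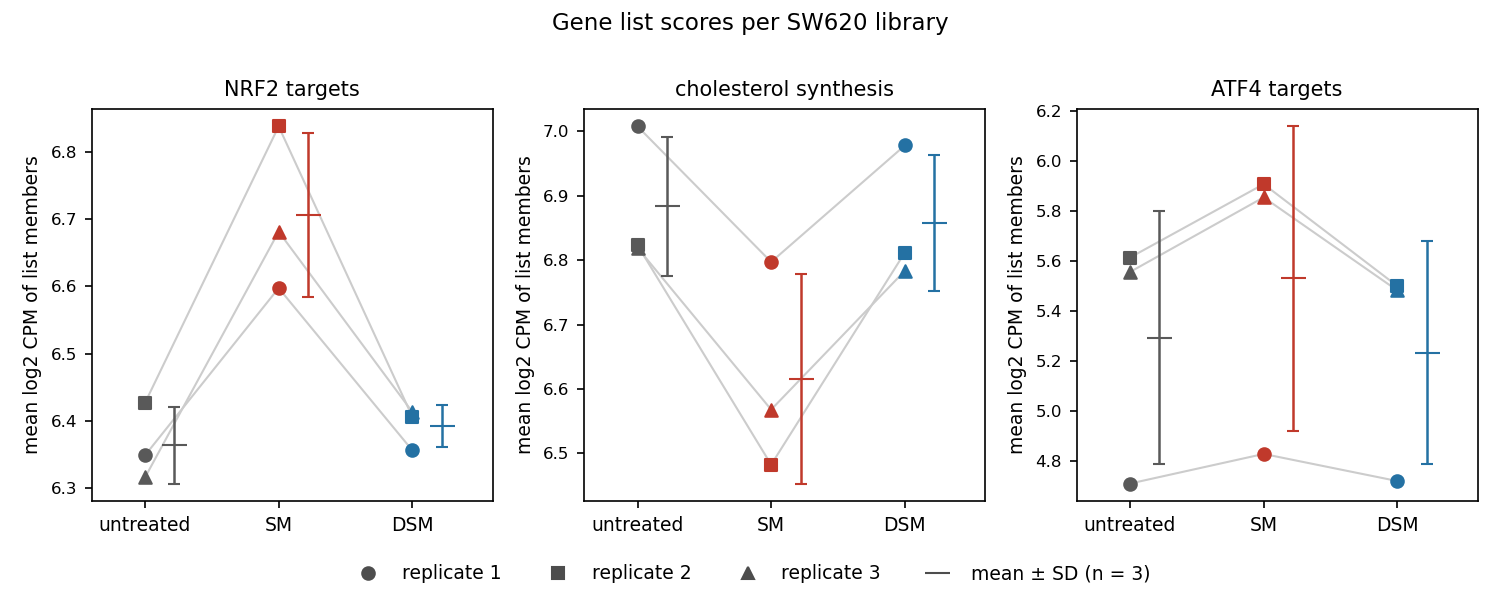
Mean log2 CPM of the members of 3 gene lists in each SW620 library by group, with symbols for the replicate number, grey lines joining libraries of the same number, and bars for the mean ± SD (n = 3). The NRF2 score is highest and the cholesterol score lowest with SM within each replicate number, while the ATF4 scores of the libraries numbered 1 lie far below all others.

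The cholesterol synthesis list held 26 tested genes, and 25 of them had a negative fold change with SM. Its score was 0.27 lower (interval of the difference -0.49 to -0.05) and lower in 3 of 3 pairs, and camera called it (adjusted p = 6.15e-33, and adjusted p = 0.316 with an estimated correlation). No member passed over all genes, and 8 passed when adjusted over the list alone. With the block 20 members fell and 0 rose, 25 when adjusted over the list alone (adjusted p = 0.0959 with an estimated correlation, and 0.0128 by fry). HMGCS1, the synthase upstream of HMG-CoA reductase, averaged 257 ± 49.6 CPM with SM and 350 ± 53.7 CPM without. It fell by 0.45 on the log2 scale (SE 0.04) in the blocked fit, MVD by 0.39 (SE 0.04), ACAT2 by 0.33 (SE 0.04) and the squalene synthase gene FDFT1 by 0.28 (SE 0.03). In the fatty acid synthesis list, 16 of 17 members had a negative fold change (camera adjusted p = 0.00309, and adjusted p = 0.822 with an estimated correlation). With the block SREBF1, FASN and SCD fell, while ME1, the cytosolic malic enzyme, rose (adjusted p = 0.26 with an estimated correlation). ME1 is also a member of the NRF2 list. Fatty acid synthesis lost its camera call without untreated replicate 1 (0.661), SM replicate 2 (0.152) or SM replicate 3 (0.121), and its mean turned to 0.0091 without untreated replicate 1.

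ATF4 targets, genes of amino acid synthesis and transport and of the integrated stress response, had 33 of 36 positive fold changes with SM. The list passed (adjusted p = 2.85e-04, and adjusted p = 0.892 with an estimated correlation), but its score difference of 0.24 had an interval of -0.64 to 1.11, since the libraries numbered 1 held the list far lower in every group. With the block that interval was 0.11 to 0.37 and 15 members rose, 20 when adjusted over the list alone (adjusted p = 0.247 with an estimated correlation). Among them STC2 rose by 0.39 (SE 0.04), VEGFA by 0.39 (SE 0.05), the cystine transporter gene SLC7A11 by 0.30 (SE 0.04) and the serine synthesis gene PHGDH by 0.27 (SE 0.04). ATF4 itself had a blocked log2 fold change of 0.21 (SE 0.07, adjusted p = 0.158) and DDIT3 one of 0.29 (SE 0.12, adjusted p = 0.293). The cytosolic aminoacyl-tRNA synthetases passed only with the block (adjusted p = 2.58e-05, and adjusted p = 0.322 with an estimated correlation), with SARS1, GARS1, EPRS1 and CARS1 higher and 0 of 20 lower. Hypoxia targets likewise passed only with the block (adjusted p = 0.0387, and adjusted p = 0.26 with an estimated correlation). Its 3 members that rose were STC2 and VEGFA, which the ATF4 list also holds, and MXI1. Without the block the ATF4 call was lost when leaving out untreated replicate 1 (0.96), SM replicate 2 (0.435) or SM replicate 3 (0.179), by camera adjusted p. The mean log2 fold change of its members, 0.27, was 0.049 without untreated replicate 1, 0.10 without SM replicate 2 and 0.12 without SM replicate 3, against 0.42 without untreated replicate 2 and 0.53 without SM replicate 1.

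The ferroptosis suppressor, glutathione and iron handling lists share 6, 6 and 3 members with the NRF2 list. The ferroptosis suppressor list passed as higher (adjusted p = 0.00346, and adjusted p = 0.417 with an estimated correlation), and with the block 6 members rose and 3 fell. All 6 that rose, among them TXNRD1 at 0.38 (SE 0.03), are also NRF2 targets, whereas SCD, HSPB1 and DHCR7 fell. The glutathione and peroxide list passed (adjusted p = 0.00815, and adjusted p = 0.392 with an estimated correlation), although 17 of its 34 members had negative fold changes. With the block 6 of its members rose, of which 5 are in the NRF2 list. The other was GPX2, which the NRF2 list does not hold. Its absence from that list does not place GPX2 outside the NRF2 response. The iron handling list passed (adjusted p = 0.0186, and adjusted p = 0.316 with an estimated correlation) with HMOX1, FTL and FTH1 as its 3 members higher under the block, while 11 of 23 had negative fold changes. The autophagy list passed (adjusted p = 4.58e-04, and adjusted p = 0.316 with an estimated correlation). Its only member that rose under the block was SQSTM1, which encodes the cargo receptor p62, at 0.43 (SE 0.04). The autophagy list shares 0 members with the NRF2 list as fixed. That does not show that SQSTM1 rose apart from the NRF2 response. Camera no longer called the glutathione list without SM replicate 2 (0.152), iron handling without untreated replicate 3 (0.114) or SM replicate 1 (0.0615) and autophagy without SM replicate 1 (0.0592).

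MYC rose by 0.41 (SE 0.04) in the blocked fit, from 686 ± 78.5 to 916 ± 159 CPM, and was the only called member of the ribosome biogenesis and MYC target list (score 0.057 higher, adjusted p = 4.33e-04, and adjusted p = 0.892 with an estimated correlation). The MAPK immediate early list passed (adjusted p = 0.0232, and adjusted p = 0.892 with an estimated correlation), and with the block FOS, FOSB and MYC rose and JUND and PHLDA1 fell. The ER unfolded protein response list passed as lower (adjusted p = 4.58e-04, and adjusted p = 0.316 with an estimated correlation). With the block 8 of its 27 members fell, among them the ER chaperone genes HSPA5 by 0.22 (SE 0.03), CALR by 0.27 (SE 0.03) and PDIA4 by 0.21 (SE 0.03). PPP1R15A, a phosphatase subunit gene, rose by 0.27 (SE 0.04). The mean of the ribosome biogenesis list was 0.017 without untreated replicate 1 and 0.021 without SM replicate 2, against 0.087 without untreated replicate 2 and 0.11 without SM replicate 1. The camera call of this list was lost without untreated replicate 1 (0.574) or SM replicate 2 (0.335), and that of the MAPK list without untreated replicate 3 (0.846), SM replicate 1 (0.142) or SM replicate 2 (0.711).

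The G2 and M phase list was 0.052 lower (adjusted p = 1.35e-05, and adjusted p = 0.316 with an estimated correlation), with ECT2 and ANLN lower under the block. MKI67, the proliferation marker, had a blocked log2 fold change of -0.12 (SE 0.04) that did not pass (adjusted p = 0.0965). TGF-beta and BMP targets passed as lower (adjusted p = 0.017, and adjusted p = 0.822 with an estimated correlation), and with the block ID1, BAMBI, BMP4, TGFBI and BMPR2 fell. With the block alone, 4 further lists passed as lower. They were Wnt targets and intestinal stem cell genes (adjusted p = 0.00502, and adjusted p = 0.26 with an estimated correlation), epithelial genes (0.00727, and adjusted p = 0.317 with an estimated correlation), mesenchymal transition genes (0.014, and adjusted p = 0.599 with an estimated correlation) and the goblet and enteroendocrine markers (0.0268, and adjusted p = 0.26 with an estimated correlation). The epithelial score rose in pair 1 (0.047) and fell in pairs 2 and 3 (-0.028 and -0.051), while the other scores fell in every pair. NKD1, SOX4, KRT19, VIM, TNC and AGR2 were among the members of these lists that fell. Among genes of at least 5 CPM, those with the largest blocked falls were LRRN4 at -0.69 (SE 0.10), FGFBP1 at -0.54 (SE 0.06) and TNC, a matrix glycoprotein, at -0.50 (SE 0.06). Below the rises of the pseudogene NMRAL2P and of AKR1C1, AKR1C2 and HMOX1, HTRA3, ZNF469 and TBC1D4 rose by 0.74 (SE 0.10), 0.74 (SE 0.06) and 0.65 (SE 0.10). TGF-beta and BMP targets lost the camera call without untreated replicate 1 (0.574), SM replicate 2 (0.213) or SM replicate 3 (0.364).

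Nuclear genes of the mitochondrial ribosome and respiratory chain showed small differences with SM. The score difference was 0.019 for the small mitochondrial ribosomal subunit (interval -0.048 to 0.086), -0.017 for the large subunit (-0.086 to 0.052) and -0.020 for complex I (-0.089 to 0.049). ATP synthase subunits passed as lower by 0.048 (adjusted p = 0.0193, and adjusted p = 0.746 with an estimated correlation), with no member called. The mRNAs encoded by mitochondrial DNA were not analysed here. GPX4 had a log2 fold change of 0.03 (SE 0.05), LGR5 of -0.07 (SE 0.13), PROM1 of 0.06 (SE 0.08), CD44 of 0.17 (SE 0.09) and CDKN1A of 0.15 (SE 0.20), none of them called with or without the block. The same held for TFRC at 0.18 (SE 0.09), ACSL4 at -0.12 (SE 0.14), and the metallothionein genes MT2A at 0.17 (SE 0.11) and MT1X at 0.27 (SE 0.22). GDF15 passed with the block at 0.28 (SE 0.04) and the asparagine synthetase gene ASNS at 0.44 (SE 0.11). Endothelial markers passed as lower (adjusted p = 0.0232, and adjusted p = 0.392 with an estimated correlation), but their most abundant members lay near 2 CPM, with EGFL7 at 2.28 ± 0.202 against 2.48 ± 0.396 CPM. Replication-dependent histones also passed (adjusted p = 0.0383, and adjusted p = 0.892 with an estimated correlation). Their level in this poly(A) RNA was low, with scores of -0.31 to 0.37 log2 CPM over the 9 libraries. Neither endothelial markers nor histones passed with the block (0.107 and 0.126). Fibroblast, leukocyte and neural or muscle markers did not pass (0.994, 0.588 and 0.625). Camera no longer called ATP synthase without untreated replicate 1 (0.219), untreated replicate 3 (0.127), SM replicate 1 (0.0996) or SM replicate 3 (0.121), endothelial markers without untreated replicate 1 (0.289), untreated replicate 2 (0.0607), SM replicate 2 (0.152) or SM replicate 3 (0.121) and histones without untreated replicate 1 (0.615), SM replicate 2 (0.185) or SM replicate 3 (0.81). The histone mean, -0.14, turned to 0.14 without untreated replicate 1 and 0.017 without SM replicate 3.

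In total 16 of 52 lists passed camera for SM against untreated, 8 in each direction, and none passed with an estimated correlation or by fry. Leaving out any 1 untreated library, SM replicate 2 or SM replicate 3 left 0 genes called in the fit without the block, and a fit on these 6 libraries alone also called 0.

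The second comparison asked the same of DSM. No gene differed between DSM and untreated cells in edgeR's test, with or without the replicate block, and 103 and 650 genes had an unadjusted p under 0.05. DESeq2 and limma voom called 0 genes without the block, and with it voom called 0 and DESeq2 only NOX5, a gene with near-zero counts named here after its values were seen. AKR1C1 averaged 42.5 ± 8.48 CPM with DSM against 42.2 ± 9.68 CPM without, HMOX1 34.8 ± 4.28 against 34.6 ± 7.39 CPM and HMGCS1 342 ± 52.8 against 350 ± 53.7 CPM (SD, n = 3). The genes called for SM had slightly higher means with DSM, none of them called: GPX2 289 ± 3.61 against 282 ± 3.18 CPM and AKR1C3 77.2 ± 4.50 against 72.4 ± 3.18 CPM, each in 3 of 3 pairs, and AKR1C2 10.2 ± 0.228 against 9.27 ± 0.993 CPM. Their log2 fold changes were 0.04 (SE 0.04), 0.09 (SE 0.06) and 0.13 (SE 0.10). The NRF2 score difference was 0.028 (interval -0.113 to 0.169, with the block -0.068 to 0.124), and that of cholesterol synthesis -0.026 (-0.244 to 0.193, with the block -0.098 to 0.047).

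Among the 10294 genes with a mean of at least 5 CPM, the 95% interval of the DSM fold change lay within 2-fold for 99.4% and within 1.5-fold for 97.0%, and with the block within 1.5-fold for 99.98%. Of the fixed genes, SLC7A11 had a log2 fold change of -0.02 (SE 0.22), FTH1 of -0.02 (SE 0.06), TFRC of 0.01 (SE 0.09), MKI67 of 0.04 (SE 0.05) and LGR5 of 0.09 (SE 0.13). GPX4, ACSL4, ATF4, DDIT3, ASNS, GDF15, CDKN1A, PROM1, CD44, MT2A and MT1X lay between -0.05 for DDIT3 (SE 0.31) and 0.09 for MT1X (SE 0.22). Without the block the 5 genes with the smallest p were SNORD24, BOLA2-SMG1P6, LOC400684, STAR and ZNF781, each at or below 1.66 CPM in untreated cells. The 5 genes with the smallest blocked p were UGDH-AS1 at 0.19 (SE 0.04, adjusted p = 0.493), and KANTR, CRLS1, MTRNR2L8 and PDXP, each with an adjusted p of 0.999. UGDH-AS1 is antisense to UGDH, and no strand setting of the counting is given in the sources used here.

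Camera called 3 lists as lower with DSM, cytosolic ribosomal proteins by 0.021, complexes II to IV by 0.031 and the large mitochondrial ribosomal subunit by 0.027 on the log2 scale. Their adjusted p were 0.0433, 0.0433 and 0.0458 (adjusted p = 0.936 with an estimated correlation for each), no member was called, and the score intervals of all 3 included 0. With the block 9 lists passed, all lower. The 6 added were complex I (adjusted p = 0.752 with an estimated correlation), ATP synthase, one-carbon and nucleotide synthesis, heat shock and ATF4 targets (adjusted p = 0.551 with an estimated correlation for each of these 4), and cholesterol synthesis (adjusted p = 0.701 with an estimated correlation). Their blocked score differences lay between -0.059 for ATF4 targets (interval -0.188 to 0.069) and -0.022 for complex I (-0.085 to 0.042). No list passed by fry, and 0 lists passed without the low-count filter. By camera adjusted p, ribosomal proteins lost the call without untreated replicate 1 (0.201), untreated replicate 3 (0.0884), DSM replicate 2 (0.0927) or DSM replicate 3 (0.876), complexes II to IV without untreated replicate 1 (0.201), untreated replicate 3 (0.128), DSM replicate 2 (0.16) or DSM replicate 3 (0.547), and the large mitochondrial subunit without untreated replicate 2 (0.0634), untreated replicate 3 (0.136), DSM replicate 2 (0.0881) or DSM replicate 3 (0.547). Without DSM replicate 1 the means were -0.040 for ribosomal proteins and -0.046 for complexes II to IV, and without DSM replicate 3 that of ribosomal proteins was -0.0042. The count of 3 lists became 10, 8 and 5 without untreated replicates 1, 2 and 3, and 10, 8 and 2 without DSM replicates 1, 2 and 3. With the block the 9 became 5, 10 and 1, and 19, 7 and 0, in the same order.

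The third comparison set SM against DSM at the same concentration and time, compounds that differ by an aldehyde against an alcohol on the streptose sugar. By camera, NRF2 targets were higher and cholesterol synthesis genes lower with SM than with DSM, calls lost when that correlation was estimated (adjusted p = 0.0711 and adjusted p = 0.41 with an estimated correlation). The NRF2 score was 0.31 higher (interval 0.17 to 0.45) and the cholesterol score 0.24 lower (interval of the difference -0.46 to -0.024), each in 3 of 3 pairs. No single gene passed in edgeR's test without the block, where 396 genes had an unadjusted p under 0.05, while voom called 0 and DESeq2 8, all higher with SM. With the block 606 genes passed, 270 higher and 336 lower with SM. AKR1C1 differed by 1.04 (SE 0.05), HMOX1 by 0.79 (SE 0.06), AKR1C2 by 0.78 (SE 0.07) and OSGIN1 by 0.68 (SE 0.07) in the blocked fit. The blocked count of 606 lay between 265 and 326 when SM replicate 3 (326), DSM replicate 2 or DSM replicate 3 (265) was left out. DESeq2's 8 genes were AKR1C2, AKR1C3, GPX2, OSGIN1, UGDH, TXNRD1, SQSTM1 and HMOX1.

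The 5 genes with the smallest p without the block were AKR1C3 at 0.46 (SE 0.06, adjusted p = 0.115), AKR1C2 at 0.79 (SE 0.10, adjusted p = 0.115), GPX2 at 0.25 (SE 0.04, adjusted p = 0.128), OSGIN1 at 0.69 (SE 0.10, adjusted p = 0.178) and UGDH at 0.35 (SE 0.05, adjusted p = 0.178). NRF2 targets passed camera (adjusted p = 1.58e-47, and adjusted p = 0.0711 with an estimated correlation), with 0 members called over all genes and 18 when adjusted over the list alone. With the block 24 of 33 members were higher with SM (adjusted p = 0.121 with an estimated correlation). Cholesterol synthesis passed (adjusted p = 4.04e-25, and adjusted p = 0.41 with an estimated correlation), with 0 members called over all genes and 3 when adjusted over the list alone. With the block 19 of 26 members were lower (adjusted p = 0.121 with an estimated correlation), led by HMGCS1 at -0.42 (SE 0.04) and MVD at -0.35 (SE 0.04). Both lists also passed by fry with the block (adjusted p = 0.0202 for each).

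ATF4 targets passed with 35 of 36 fold changes positive (adjusted p = 7.21e-07, and adjusted p = 0.808 with an estimated correlation). With the block 21 members were higher with SM, among them SESN2 at 0.67 (SE 0.07), STC2 at 0.40 (SE 0.04) and PHGDH at 0.39 (SE 0.04) (adjusted p = 0.209 with an estimated correlation, and 0.0325 by fry). Aminoacyl-tRNA synthetases passed (adjusted p = 0.0328, and adjusted p = 0.808 with an estimated correlation), with 7 of 20 higher under the block, as did ribosome biogenesis and MYC targets (adjusted p = 3.30e-05, and adjusted p = 0.808 with an estimated correlation) with MYC, POLR3G and RRP12. The G2 and M phase list was lower with SM (adjusted p = 1.85e-04, and adjusted p = 0.443 with an estimated correlation), with ANLN, CENPE, DLGAP5 and MKI67 lower under the block. The ER unfolded protein response list was also lower (adjusted p = 8.22e-04, and adjusted p = 0.443 with an estimated correlation), with 9 members lower, CALR at -0.29 (SE 0.03) among them, and 2 higher. A further 9 lists passed for SM against DSM. Higher with SM were glutathione and peroxide metabolism (adjusted p = 0.41 with an estimated correlation), ferroptosis suppressors and autophagy (adjusted p = 0.443 with an estimated correlation for each), and MAPK immediate early genes and the machinery of mitochondrial DNA expression (adjusted p = 0.808 with an estimated correlation for each). Lower were fatty acid synthesis and replication-dependent histones (adjusted p = 0.808 with an estimated correlation for each), colonocyte differentiation (adjusted p = 0.586 with an estimated correlation) and the goblet and enteroendocrine markers (adjusted p = 0.443 with an estimated correlation). The histone scores were low here too, at -0.31 to 0.37 log2 CPM. LGR5, an intestinal stem cell gene, differed by -0.17 (SE 0.05, blocked adjusted p = 0.0401). GPX4 differed by 0.04 (SE 0.04) and PROM1 by 0.04 (SE 0.06), neither called. By camera adjusted p, ATF4 targets lost the call without DSM replicate 1 (0.145), aminoacyl-tRNA synthetases without SM replicate 2 (0.459), SM replicate 3 (0.462) or DSM replicate 1 (0.569), and ribosome biogenesis without SM replicate 2 (0.104) or DSM replicate 1 (0.073). The same held for MAPK genes without SM replicate 1 (0.0739), SM replicate 2 (0.284), DSM replicate 1 (0.159) or DSM replicate 3 (0.316), autophagy without SM replicate 1 (0.186) or DSM replicate 3 (0.316), and the mitochondrial DNA machinery without SM replicate 2 (0.331), SM replicate 3 (0.135), DSM replicate 1 (0.262) or DSM replicate 3 (0.316). Fatty acid synthesis lost it without SM replicate 2 (0.234), SM replicate 3 (0.159) or DSM replicate 1 (0.392), histones without SM replicate 3 (0.14) or DSM replicate 1 (0.569), colonocyte differentiation without SM replicate 2 (0.284), DSM replicate 1 (0.0893) or DSM replicate 3 (0.316), and goblet and enteroendocrine markers without SM replicate 2 (0.0603).

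Of the nuclear mitochondrial lists, complex I differed by 0.0018 between SM and DSM (interval -0.067 to 0.070), complexes II to IV by 0.0060 (-0.068 to 0.080) and the large mitochondrial ribosomal subunit by 0.0098 (-0.060 to 0.079). Altogether 16 lists passed for SM against DSM, 9 higher and 7 lower, none with an estimated correlation or by fry. With the block 22 passed camera, 0 passed with an estimated correlation and 18 passed fry. The 6 added were iron handling, hypoxia targets and mitochondrial chaperones, higher, and Wnt, epithelial and mesenchymal genes, lower (adjusted p = 0.209, 0.209, 0.342, 0.209, 0.263 and 0.540 with an estimated correlation). Without the block the 16 became 25 without SM replicate 1 and 10 without SM replicate 2. In the blocked fit the fixed genes SLC7A11, FTH1 and GDF15 were higher with SM by 0.32 (SE 0.04), 0.20 (SE 0.04) and 0.24 (SE 0.04), and MKI67 was lower at -0.16 (SE 0.04). TFRC, ACSL4, ATF4, DDIT3, ASNS, CDKN1A, CD44, MT2A and MT1X did not pass, with values from -0.11 for ACSL4 (SE 0.04) to 0.37 for ASNS (SE 0.11, adjusted p = 0.0538).

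**Figure D3:**
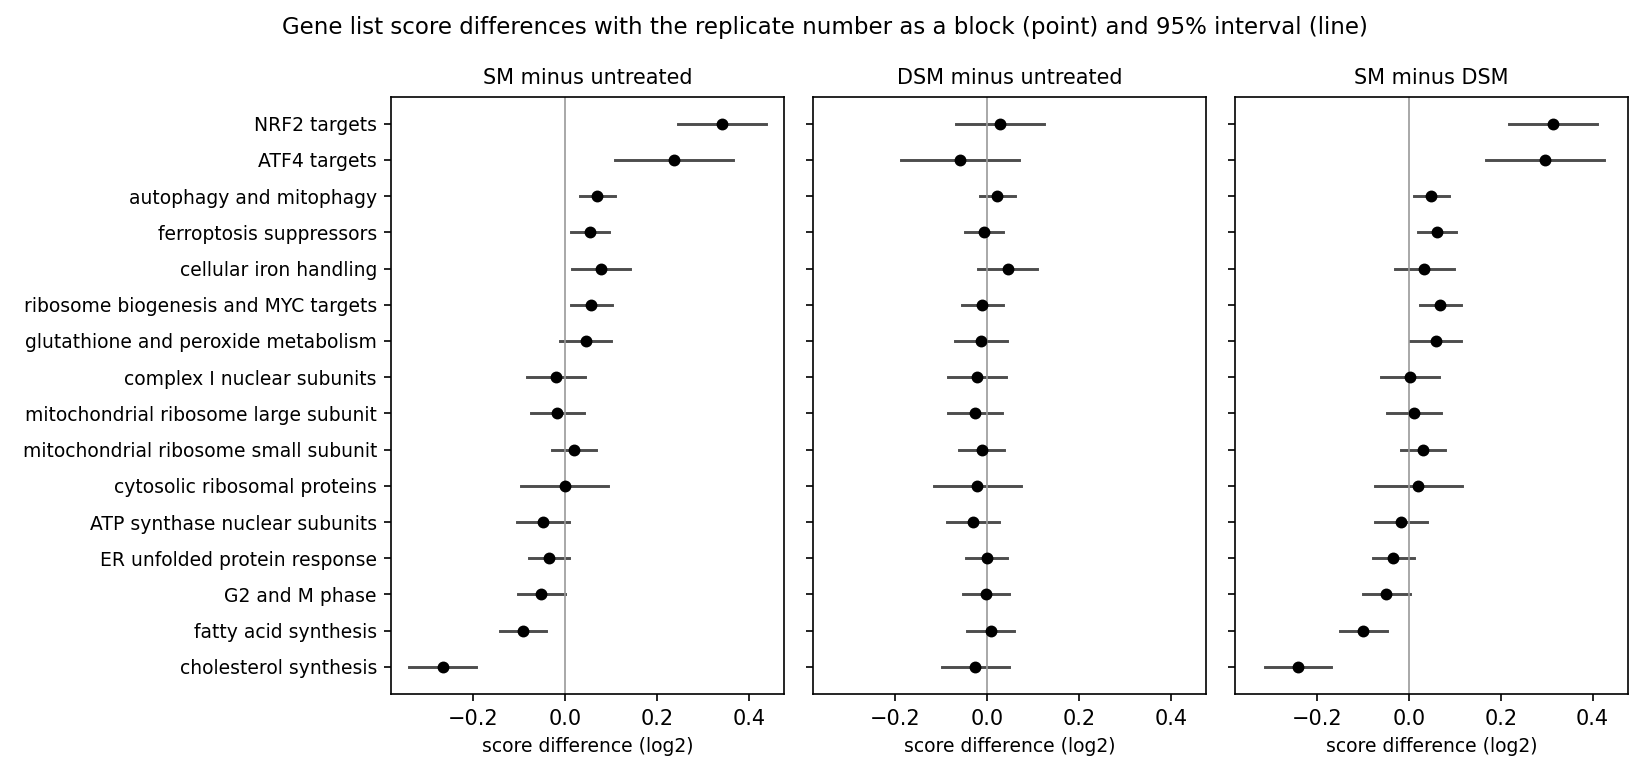
Differences in list score (mean log2 CPM of members) between groups for 16 of the 52 gene lists, from limma fits with the replicate number as a block, with points for the difference and lines for its 95% interval. NRF2 targets (0.34 and 0.31) and cholesterol synthesis (-0.27 and -0.24) lie away from 0 for SM against untreated and against DSM, while each DSM against untreated interval drawn here includes 0. The lists drawn are a selection and leave out larger DSM differences. Endothelial markers (6 tested genes) were lower with DSM than untreated in every pair (-0.165, -0.421 and -0.209). Goblet and enteroendocrine markers (9 tested genes) were higher in every pair (0.0959, 0.188 and 0.116). Camera called neither list for DSM.

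With the block, 144 genes were higher and 173 lower with SM in both of its comparisons, and 0 went opposite ways. Independent lists would share 3.23 and 5.18, but both comparisons use the same SM libraries, so part of the overlap may come from those libraries alone. Across all tested genes, which are not independent replicates, the fold changes of SM and DSM against the shared untreated libraries had a correlation of 0.376 and a covariance of 0.0137. Simulated unchanged groups with the replicate effects kept gave a median correlation of 0.473 (0.443 to 0.490) and a median covariance of 0.0131 (0.0118 to 0.0138), so the observed correlation lay below the simulated range and the observed covariance within it, 0.000672 above its median. Without replicate effects the simulated medians were 0.485 (0.463 to 0.521) and 0.0233 (0.0220 to 0.0262), and both observed values lay below these ranges. That setting drew its noise from the fit without the block. Differences between replicate numbers thus entered it as independent noise per library, unlike the real libraries, so no conclusion is drawn from it. The correlation is no larger than the shared untreated libraries alone gave in the simulations with replicate effects kept.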

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

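The tests in this part chosen only after the data were seen are the blocked forms of DESeq2, voom, fry, the estimated correlation and leaving out a library, thinning, and leaving out the libraries numbered 1. For SM against untreated, 3 genes were called, and the count was 5 with no filter on low counts, 12 with DESeq2, 0 with only the 2 groups compared, 428 with the replicate block, 380 with DESeq2 and the block, 438 with voom and the block, and 427 after thinning with the block. It was 73 without the libraries numbered 1 and 308 with the block as well. Leaving out 1 library gave 0 to 3, and 149 to 569 with the block. For SM against DSM, 0 genes were called, and the count was 3 with no filter, 8 with DESeq2, 606 with the block, 495 with DESeq2 and the block, 590 with voom and the block, 587 after thinning with the block, 186 without the libraries numbered 1, and 627 with the block as well. Leaving out 1 library gave 0 each time, and 265 to 846 with the block. For DSM against untreated the count of 0 became 1 with DESeq2 and the block (NOX5) and 1 with the block without the libraries numbered 1 (DDIT4), both chosen after their values were seen, and was 0 otherwise. The rise with the block is taken up below for SM against untreated, and the causes of the other changes were not tested. Fewer samples leave fewer degrees of freedom, yet the counts rose to 73 and 186 without the libraries numbered 1.

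The lists called for SM against untreated went from 16 to 0 with an estimated correlation, 0 with fry, 0 with an estimated correlation and the block, and 6 with fry and the block. With no filter on low counts 14 passed, and 3 of the 16 lost the call. Leaving out 1 library gave 12 to 22, and 17 to 24 with the block. For DSM the 3 lists became 0 with no filter, 9 with the block, 5 after thinning with the block, and 0 with an estimated correlation or fry, each with and without the block. With 1 library left out it was 2 to 10, and 0 to 19 with the block. For SM against DSM the 16 lists became 0 with an estimated correlation, 0 with fry and 0 with an estimated correlation and the block. With no filter on low counts 14 passed, and 2 of the 16 lost the call. The count was 10 to 25 with 1 library left out, and 16 to 27 with the block. The replication-dependent histone mean for SM against untreated, -0.14, turned to 0.14 without untreated replicate 1 (camera adjusted p = 0.615) and 0.017 without SM replicate 3 (0.810). Leaving out 1 library gave -0.18 to 0.14. The correlation of the SM and DSM fold changes was 0.244 with the stricter filter and 0.256 to 0.565 with 1 library left out. The cause was not tested.

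AKR1C3 kept a log2 fold change of 0.52 to 0.58 with 1 library left out of the fit without the block, with an edgeR adjusted p of up to 0.228. GPX2 also missed the threshold with library totals (0.0965) and without robust estimation (0.0568). Beyond the calls given here and beside the results, the block changed no call of a main result. The planned scaling without genes encoded by mitochondrial DNA gives no value of its own, since the table used holds none of them.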

Other observations

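The tests along the axis that separates the libraries numbered 1 from the others, and those after thinning, were chosen only after the result was seen. In a fit with group and replicate number as terms, 6554 genes differed between the libraries numbered 2 and 3 and those numbered 1, 3171 higher and 3383 lower, 263 of them at least 2-fold, against 575 between 3 and 2. ATF4 targets led the difference, with 33 of 36 higher in 2 and 3, 1 lower and a mean log2 difference of 1.02 (camera adjusted p = 4.53e-64, and adjusted p = 0.222 with an estimated correlation). The activin subunit gene INHBE lay at 0.771 to 0.871 CPM in the libraries numbered 1 and 5.93 to 11.6 CPM in the others. PHGDH, the first enzyme of serine synthesis, lay at 50.6 to 62.4 against 160 to 220 CPM. Camera also called aminoacyl-tRNA synthetases (13 of 20 higher in 2 and 3, adjusted p = 0.222 with an estimated correlation) and S phase genes (36 of 46 higher, adjusted p = 0.240 with an estimated correlation). Cholesterol synthesis genes were lower (22 of 26, mean -0.21, adjusted p = 0.250 with an estimated correlation), and so were TNC at 197 to 346 against 541 to 715 CPM and the tubulin gene TUBA1A at -1.48. These genes were chosen after their values were seen, and the labels do not say what the numbers share.

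The number of genes called for SM rose from 3 to 428 when the replicate number was a block. Among 36 assignments of numbers within groups, the labels' own gave 428 calls, the highest other 204 and the median of the others 0. That argues against a fit that calls genes in any pairing, and is consistent with differences shared by libraries of the same number. The splits were too few for a share under 0.05. Without the block, 1 of 10 splits gave as many genes for SM against untreated (real 3, highest other 0), and 10 of 10 for DSM against untreated and for SM against DSM (real 0, highest other 0 in each), while 1 of 4 within-pair splits did with the block for SM against untreated (428, highest other 0) and 1 of 4 for SM against DSM (606, highest other 0).

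By camera, NRF2 targets were higher and cholesterol synthesis genes lower with SM than without, calls lost when the correlation between genes was estimated (with the block, adjusted p = 0.0959 with an estimated correlation for each). Thinned to the smallest total, with the block, the score differences were 0.34 (interval 0.25 to 0.44) and -0.26 (-0.34 to -0.19). Thinning could move scores of 6.32 to 7.01 log2 CPM little, so it is a weak test of the lower depth of SM replicate 2. Pairs 1 and 3, which do not hold that library, differed by 0.25 and 0.36 for NRF2 targets. For cholesterol synthesis they differed by -0.21 and -0.25. These values argue against that depth as the only source of the 2 differences. Without the AKR1C genes the NRF2 difference was 0.29 (0.20 to 0.39), so reads shared among these paralogs do not account for it. After a loess on GC content and length, which explained 0.246% of the variance, the list means were 0.34 (0.23 to 0.47) and -0.26 (-0.31 to -0.22), with all members matched. The intervals after the loess came from a bootstrap over list members, so they hold no spread between libraries. An effect of SM itself and an unequal state of the SM cultures stay open, and the splits above count genes and were not run on these lists.

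The SM effect ran partly along the replicate axis: across 10294 genes, which are not independent replicates, its correlation with the difference between the libraries numbered 2 and 3 and those numbered 1 was 0.492 (Spearman 0.420), against -0.226 (Spearman -0.173) for DSM. With the slope of the SM effect on that axis removed (0.201, 1 slope for all genes), the ATF4 mean went from 0.26 to 0.057 (0.020 to 0.094). Cholesterol synthesis kept -0.22 (-0.26 to -0.18) and NRF2 targets 0.32 (0.22 to 0.45). These intervals came from a bootstrap over list members and hold no spread between libraries. A shift with that common slope does not account for the latter lists. Their mean differences along the axis were -0.21 and 0.081, so that slope could remove little of either mean. A steeper slope for their genes was not tested. The slope was not removed for other lists, such as aminoacyl-tRNA synthetases, whose mean difference along the axis was 0.26. With an axis from the DSM libraries alone the correlation was 0.465 and the ATF4 mean 0.11. As a hypothesis, SM may shift amino acid and stress genes in the direction in which these cultures already differed, and an unequal state of the SM cultures could not be excluded. Dividing each of several cultures between SM, DSM and no drug only at the time of dosing would test this. The groups would then start from the same culture, so a shift with SM would not come from an unequal state at the start. RNA taken just before dosing would show where each culture lay along the axis.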
